A study of Mus musculus with 17 samples.

How the data were processed

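Gene expression was measured in mouse marrow cells with 17 single-colour Illumina arrays of 45281 probes, from 100 ng of RNA each, per the labels' protocols. The intensity values are mean bead signals per probe and array, written by GenomeStudio per the submitters' processing notes (version not given) and deposited without background subtraction or normalization. The detection p-value of each probe, also per the file headers as deposited, compares it with the negative control beads of the same array. The log2 values deposited as the series matrix behaved as quantile-normalized intensities of each dataset without background correction, with medians of 6.47 in dataset A and 6.80 in dataset B. How the authors made them is not given in the sources used here, and they served as an alternative. Their direction is that of the intensities (rank correlations of 0.99999 or more), they are not centred per gene, and the scale was read from the values.

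Groups came from the sample titles. The intensity header of cluster array 1 of dataset A appears on 2 columns, so the second of them was taken as a cluster array of dataset A without a number. The detection column beside it is headed cluster array 2, and its ranks correlated at 0.99999 with cluster array 2 of the series matrix and at most 0.805 with any other array, but values and column order were not used to assign numbers. For miR-155, 2 arrays were analysed here, although the design text speaks of independent biological triplicates. P-values measure the spread among these samples. Of 136 pairs of arrays, 0 held identical values. The lowest signal per array lay between 70.1 and 75.9 in dataset A and between 85.9 and 94.3 in dataset B, the highest between 20380 and 25844 and between 39404 and 49299.

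With R 4.3.3 and data.table (version 1.17.8), limma 3.58.1 corrected the background (normexp with controls inferred from detection p-values, offset 16) and normalized quantiles within each dataset, as the design text describes the datasets as analysed individually. Of the probes, 34885 had 1 gene symbol, 18 several and 10378 none. Gene IDs of 34807 matched the gene list of assembly GRCm38.p6, used for names only, and 0 symbols changed. Each of 19057 genes was represented by its brightest probe, and tested where that probe had a detection p-value under 0.05 on at least 2 arrays in dataset A (10272 genes) or 3 in dataset B (9389 genes). Both datasets shared 8956 genes. All groups of a dataset entered 1 limma fit (lmFit, contrasts, eBayes), and an adjusted p (Benjamini-Hochberg) under 0.05 was called. The difference of the cluster effect between datasets was an interaction contrast over 12 arrays normalized together. All p values given as adjusted p for genes come from limma.

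Gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over 84 tests, 21 lists in 4 comparisons with the empty vector. They covered primitive progenitor, neutrophil primary granule and promyelocyte, neutrophil maturation, monocyte and macrophage, erythroid, megakaryocyte, mast cell and basophil, eosinophil, lymphoid, and dendritic cell and MHC class II genes. They also covered DNA replication, mitosis, p53 target, apoptosis regulator, interferon response, cholesterol synthesis, and ribosome biogenesis and MYC target genes, and targets of miR-125, let-7, miR-99 and miR-155 named in the literature. With an estimated correlation, 0 of the 19 calls held. Median, mean and test differed in sign for some uncalled lists. With the cluster in dataset A these were primary granule, mitosis, apoptosis, interferon and miR-155 targets, and in dataset B neutrophil maturation, erythroid, dendritic cell, DNA replication, miR-99 and miR-155 targets. With miR-125a they were erythroid and let-7 targets, and with miR-155 DNA replication and apoptosis.

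The lists, groups, tests, alternatives (except a block by order, below) and rule for named genes were chosen before the data were examined. The rule took, per comparison with the empty vector, the 8 largest called rises and falls whose groups did not overlap, without unnamed gene models. It added from each list up to 4 called members, or up to 2 of the largest size where none was called, and for the direct comparisons of vectors the 5 largest called rises and falls. It also reserved the 5 called genes of smallest p for the difference between datasets and microRNA genes of the vectors, which gave none. Not every gene so taken is printed. A part of the rule on sites complementary to microRNA seeds was not run, as 3' UTR sequences were not used here. Genes named in dataset B or across comparisons because dataset A named them, and those listed as shared, were chosen after their values were seen. Of 64 calls of named genes, 28 had another detected probe of the gene, and 40 of these 43 other probes had the same sign.

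In dataset B the deviations from the group means of empty-vector and cluster arrays with the same number correlated at 0.12, 0.19 and 0.18. These lay above the set threshold of 0.1, so the numbers were taken as pairs from the data. The labels do not say that a number marks a shared mouse, culture or day, and the main fits used no block. The miR-125a arrays carry other numbers, so the labels do not pair them. Taken in order (1 with 4, 2 with 5, 3 with 6), their deviations correlated at 0.12, 0.19 and 0.22 with the empty-vector arrays and at 0.23, 0.48 and 0.29 with the cluster arrays. A block by that order was therefore added as an alternative after the data were seen. The alternatives were no background correction, median scaling, no filter or a stricter one (detection p-value under 0.01 on every array), the series matrix, all arrays normalized together, every probe, array weights, a trended robust prior, only the groups compared, a minimum fold of 1.5, the number as a block, an estimated correlation and each array left out. Slides are not given in the sources used here. Shared controls were simulated 200 times.

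The procedure was tested on simulated data with 200 of the genes changed in each of 5 runs. For the cluster in dataset A it recovered 11.9% of genes changed by a log2 of 0.5, 73.1% by 1 and 99.7% by 2. For the cluster in dataset B it recovered 24.2%, 79.7% and 97.6%, for miR-125a 23.9%, 78.8% and 98.5%, and for cluster against miR-125a 25.1%, 77.9% and 97.9%. For miR-155 it recovered 3.88%, 63.9% and 97.6%, and for cluster against miR-155 4.18%, 58.2% and 96.7%. Between 3.55% and 5.25% of calls were false. The simulated genes were independent, and no pairing or outlying array was simulated. With fewer than 200 changed genes the adjusted threshold is stricter. The shares recovered therefore do not tell how many changes were missed in the real comparisons, least of all in dataset B. Of lists of 25 independent genes shifted by a log2 of -0.3, 25 of 25 were called, and 0 of 75 unshifted lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.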

Results

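Messenger RNA was measured on 17 Illumina mouse BeadChips, arrays whose beads carry gene-specific probes and report a fluorescence intensity. The cells came from the bone marrow of C57Bl/6 mice, taken 4 days after a dose of 150 mg/kg 5-fluorouracil, a drug that kills dividing cells and leaves marrow rich in primitive ones. They grew for 7 days with stem cell factor, interleukin-11 and Flt3 ligand, and were infected with retroviral vectors carrying a green fluorescent marker. Viable cells bearing the marker were collected 5 days after the first infection. The vectors held no microRNA (empty vector), the microRNA cluster 99b/let-7e/125a, its member miR-125a alone, or miR-155. MicroRNAs are short RNAs that lower the messenger RNAs they pair with. Dataset A held 3 arrays with the empty vector, 3 with the cluster and 2 with miR-155. Dataset B held 3 arrays each with the empty vector, the cluster and miR-125a. Between 34.8% and 38.7% of probes were detected per array in dataset A, and between 34.2% and 38.9% in dataset B. The lowest share in dataset A was that of miR-155 array 2. The number of arrays, not a read depth, limits the precision. Of all probes, 0 were named for a microRNA gene of the vectors, so the overexpression itself was not measured here.

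The first comparison asked which transcripts changed with the cluster. In dataset A, 5 of 25 measured genes of neutrophil maturation and 2 of 5 eosinophil genes fell with the cluster against the empty vector, and a small set of other transcripts rose. The largest rise among the named genes was in Cited4, a transcriptional co-activator, at 4.83-fold (log2 2.27 ± 0.19, SE, 3 arrays against 3, limma adjusted p = 1.43e-05). The largest fall among them was in Ltf, the granule protein lactoferrin, which was 3.99-fold lower (SE 0.21 on the log2 scale, adjusted p = 9.41e-05). Of 10272 genes tested, 33 rose and 33 fell, with 801 at an unadjusted p under 0.05. Other rises were in Catsperz, a subunit of a sperm calcium channel (log2 1.99), the small GTPase Rab34 (1.59), the secreted protease Klk8 (1.40), the surface protein Thy1 (1.31), Maged1 (1.26), the transglutaminase Tgm2 (1.24) and Aif1l (1.19). Aif1l was detected on 1 of the 3 empty-vector arrays. Other falls were in the antimicrobial peptide gene Camp (log2 -1.89), the chitinase-like gene Chil1 (-1.89), the lectin gene Fcnb (-1.68) and the DNA-binding factor Arid3a (-1.54 ± 0.21, adjusted p = 0.00109). The stefin genes Stfa2 (-1.95), Cstdc4 (-1.94), Cstdc5 (-1.62) and Stfa1 (-1.47), which encode cysteine protease inhibitors, fell as well. These are near-identical genes, so which of them each probe measured is uncertain. Folds depended on the background correction. Without it Cited4 was 2.29-fold higher and Rab34 2.08-fold in place of 3.01-fold, both still called, and 4 of the 23 named genes moved in fold by over 1.5 times and 7 lost their call. With series matrix values Cited4 was 2.14-fold higher, 8 moved and 7 lost their call. Without a filter on dim probes 14 of the 23 lost it, and under median scaling 6.

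Of 25 measured neutrophil maturation genes, 5 fell and 0 rose with the cluster in dataset A, among them Ltf, Camp, Itgb2l (log2 -1.47) and Stfa1. Adjusted over the list alone, 13 fell and 1 rose. The list's median was -0.44 (camera adjusted p = 1.09e-12; adjusted p = 0.0876 with an estimated correlation). Of 5 measured eosinophil genes, 2 fell, Prg2 (-1.30) and Prg3 (-1.11), which encode granule proteins, and the same 2 did so adjusted over the list alone. Prg3 was detected on 1 of 3 cluster arrays. The eosinophil median was -0.12 (adjusted p = 0.00733, and adjusted p = 0.406 with an estimated correlation), and -0.00280 without empty-vector array 1 (adjusted p = 0.105). Prg2 and Prg3 each lost their call with 3 of the 6 arrays left out in turn. Of 25 monocyte and macrophage genes, 0 were called over all genes and 1 fell adjusted over the list alone. Their median was -0.20 (adjusted p = 0.000364, and adjusted p = 0.406 with an estimated correlation).

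The lists of microRNA targets named in the literature also lay lower with the cluster in dataset A. Of 26 miR-125 targets, 2 fell, Arid3a and Abtb1 (log2 -1.06), and 5 fell adjusted over the list alone. The median was -0.17 (adjusted p = 0.000364, and adjusted p = 0.0898 with an estimated correlation). Of 25 let-7 targets, 1 fell, again Arid3a, which both lists hold, and 1 did so adjusted over the list alone. Their median was -0.19 (adjusted p = 0.000763, and adjusted p = 0.434 with an estimated correlation). Of 17 miR-99 targets, 0 were called, also adjusted over the list alone, while their median was -0.23 (adjusted p = 0.00733, and adjusted p = 0.434 with an estimated correlation). The other 15 lists did not pass, with medians between -0.19 and 0.12 and a lowest adjusted p of 0.135. They covered primitive progenitors, primary granules, erythroid cells, megakaryocytes, mast cells and basophils, lymphoid cells, dendritic cells, DNA replication, mitosis, p53 targets, apoptosis, interferon response, cholesterol synthesis, ribosome biogenesis and miR-155 targets. Single members of these were called: Thy1 rose and Satb1 (log2 -0.76) fell among lymphoid genes, Fcnb fell among primary granule genes, and Cd86 (-0.76) fell among dendritic cell genes. The count of 66 genes was 36, 43 and 32 without empty-vector arrays 1, 2 and 3, and 44, 30 and 34 without cluster array 1, the cluster array that carries no number and cluster array 3. Of the 23 named genes, 16 stayed called whichever array was left out. Tgm2, Cstdc5, Prg2, Prg3, Satb1, Cd86 and Abtb1 did not, with adjusted p reaching 0.219, 0.0577, 0.129, 0.0610, 0.230, 0.205 and 0.211. The eosinophil call ended without empty-vector array 1 (adjusted p = 0.105) or a filter (0.165) and with the number as a block on series matrix values (0.0752), and the miR-99 call without the cluster array that carries no number (adjusted p = 0.125). Without that cluster array the miR-99 median was -0.10 in place of -0.23. Among the uncalled lists, ribosome biogenesis passed upward without empty-vector array 1 (adjusted p = 0.00200) or cluster array 1 (0.00782), cholesterol synthesis upward without empty-vector array 3 (0.0358) or a filter (0.0453) and with the block on series matrix values (0.0419), and mast cell and basophil genes downward without empty-vector array 2 (0.0208) and with every probe (0.0131).

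**Figure D1:**
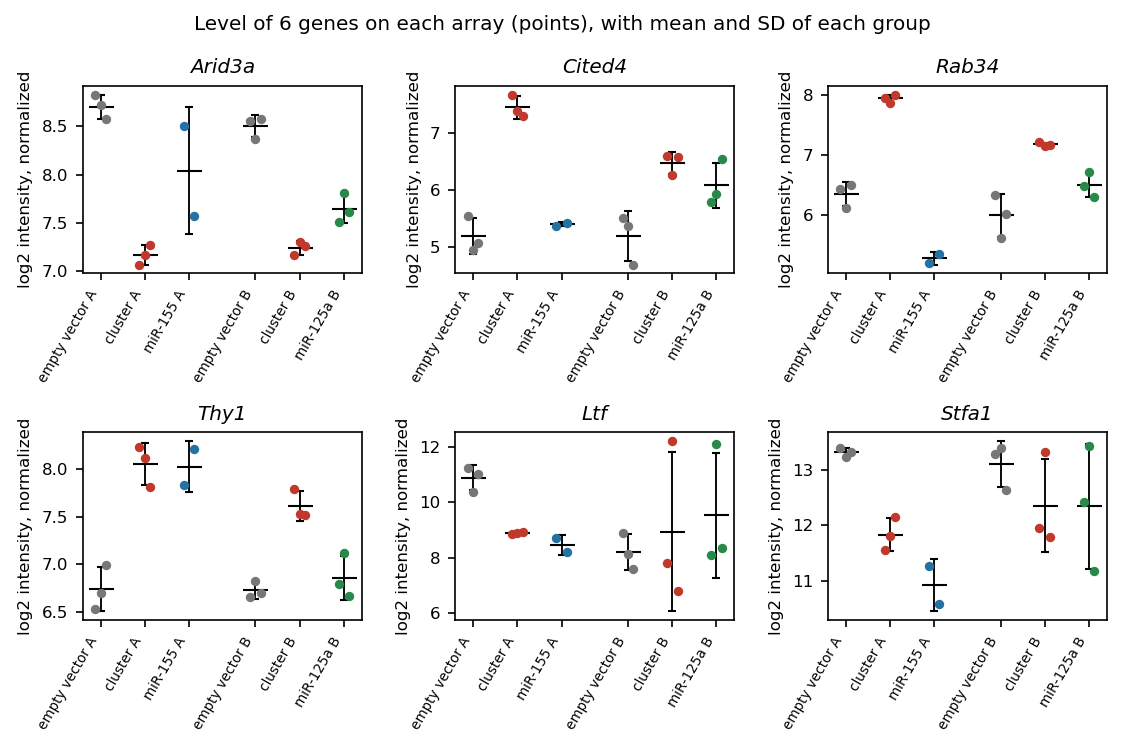
Normalized log2 intensity (vertical axes) of 6 genes on each of the 17 arrays (points), by vector and dataset (horizontal axes), with the mean and SD of each group as lines. Arid3a lay lower with the cluster in both datasets (log2 -1.54 in dataset A and -1.26 in dataset B), and Ltf spread widely in dataset B with the cluster and with miR-125a.

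The same comparison was made again in dataset B. Arid3a fell, with a log2 change of -1.26 ± 0.12 (SE, 3 arrays against 3, limma adjusted p = 0.00664), a 2.40-fold lower level, with each cluster array below each empty-vector array. It was the single call among 9389 genes, 924 of which had an unadjusted p under 0.05. Median scaling called 71 genes, 68 of them higher, around a median of all genes of 0.31, and a trended robust prior called 26. The numbers of these arrays were taken as pairs from weak correlations, not from the labels. With the number as a block Arid3a was not called (limma adjusted p = 0.216) and the count was 0, with 1078 genes at an unadjusted p under 0.05. That fit also left out the miR-125a arrays. Without them and without a block, the single call had a limma adjusted p of 0.0342 in place of 0.00664. The lost call can therefore not be laid to the pairing alone. The rises of dataset A had positive values that missed the threshold: Cited4 1.29 ± 0.24 (adjusted p = 0.148), Catsperz 1.29 ± 0.24 (0.148), Rab34 1.18 ± 0.18 (0.105), Thy1 0.89 ± 0.14 (0.105) and Klk8 0.88 ± 0.14 (0.105). Ltf stood at 0.74 ± 1.33, because cluster array 5 lay far above the others.

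Of 26 monocyte and macrophage genes in dataset B, 0 were called with the cluster, also adjusted over the list alone, and their median was -0.19 (camera adjusted p = 0.00733, and adjusted p = 0.569 with an estimated correlation). Under median scaling that median was 0.12 while the median of all genes was 0.31, so that the list again lay lower than the rest. Of 22 miR-125 targets, 1 fell, Arid3a, with 2 lower and 1 higher adjusted over the list alone. Their median was -0.12 (adjusted p = 0.00733, and adjusted p = 0.254 with an estimated correlation) and 0.18 under median scaling, where the call ended (0.0724), as it did without a filter (0.0803). Of 23 let-7 targets, 1 fell, Arid3a, with 1 lower and 2 higher adjusted over the list alone. Their median was -0.13 (adjusted p = 0.0482, and adjusted p = 0.569 with an estimated correlation) and 0.14 under median scaling. The let-7 call held in 4 of 17 alternatives, and also ended under median scaling (0.106), without background correction (0.0805) or filter (0.109), with a stricter filter (0.103), series matrix values (0.0889), every probe (0.0639), array weights (0.0714) or a trended robust prior (0.0571). Neutrophil maturation genes had a median of 0.09 (adjusted p = 0.967) that rested on cluster array 5, without which it was -0.37 and passed (0.00552), as did the eosinophil list at -0.29 (0.00457), which also passed under median scaling (0.000882). These and the other 16 lists did not pass with all arrays and quantile normalization, with medians between -0.14 and 0.11 and a lowest adjusted p of 0.155. The fit without cluster array 5 kept empty-vector array 5, where the neutrophil list also lay high, by 0.60 over the other empty-vector arrays. A fit without both was not run. The Arid3a call ended without empty-vector array 4 (adjusted p = 0.0639) or cluster arrays 4 (0.0779) or 6 (0.0631), and the count was 2 without empty-vector array 6. The monocyte call ended without empty-vector array 6 (adjusted p = 0.0599) or cluster array 6 (0.0989), and the miR-125 call without cluster array 6 (0.0553). The let-7 call ended without empty-vector arrays 4 (0.140) or 5 (0.135) or cluster arrays 4 (0.0650) or 6 (0.383).

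**Figure D2:**
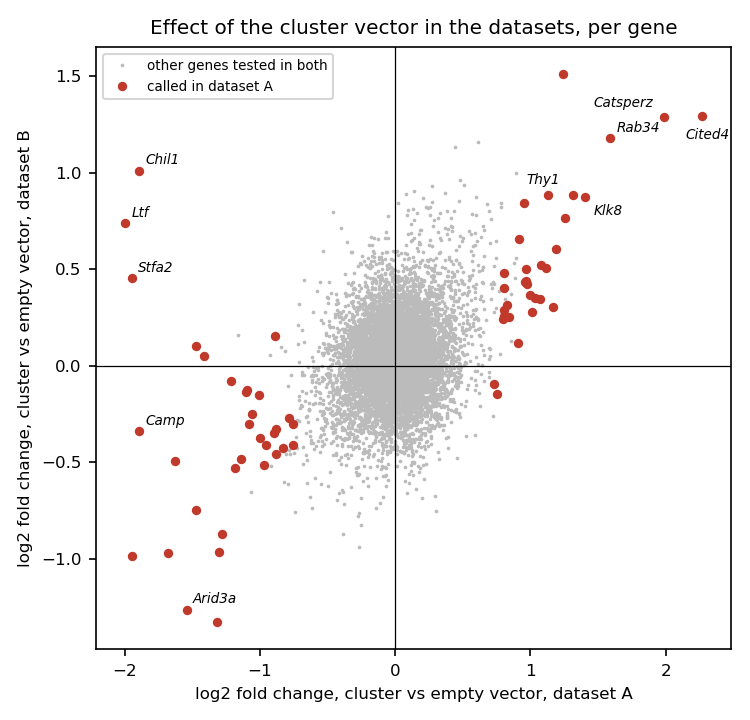
Log2 fold change of the cluster against the empty vector in dataset A (horizontal axis) and dataset B (vertical axis), 1 point per gene tested in both, with genes called in dataset A in red. Arid3a lies low on both axes, at -1.54 and -1.26, and Ltf lies low in dataset A and at 0.74 in dataset B.

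The effects of the cluster in the datasets were then set against each other. Of the 32 genes that rose in dataset A and were tested in both, 30 had a positive value in dataset B and 20 of these an unadjusted p under 0.05. Of 33 that fell, 27 had a negative value and 9 of these an unadjusted p under 0.05. Arid3a was called in both without the block, where independent lists would share 0.00368 genes, while with the block in dataset B 0 genes were called in both. Across 8956 genes, which are not independent replicates, Pearson's r was 0.27 and Spearman's rho 0.16, 1 of 6 such correlations computed. In a test of the difference itself, limma called 0 of 8956 genes, with 493 at an unadjusted p under 0.05 and a lowest adjusted p of 0.851. Cited4 differed by 0.83 ± 0.30 (adjusted p = 0.869) and Ltf by -2.75 ± 1.23 (0.869). In list tests chosen after the other results were seen, camera called 0 of the 21 lists different, with 3 at an unadjusted p under 0.05. Nearest came the neutrophil maturation list, at a median difference of -0.43 (adjusted p = 0.0523; adjusted p = 0.866 with an estimated correlation).

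The next comparison asked how far miR-125a alone, 1 member of the cluster, changed the same cells. No gene passed: limma called 0 of 9389, with 994 at an unadjusted p under 0.05 and a lowest adjusted p of 0.110. Median scaling called 2176 genes, 2173 of them higher, around a median of all genes of 0.47, and a trended robust prior called 18. The scaling evened the median of all probes, most of them undetected, and left the tested genes off centre. The count of 2176 therefore cannot be read as changes of single genes. A block that pairs the arrays by the order of their numbers, chosen after the data were seen, called 0, with 1236 at an unadjusted p under 0.05. Klk8 (log2 1.06 ± 0.14, SE, 3 arrays against 3), Arid3a (-0.86 ± 0.12) and Zfp574 (0.76 ± 0.11) shared the lowest adjusted p, and the progenitor transcription factor Sox4 (-0.81 ± 0.14) stood at 0.111. Zfp574 was chosen after its values were seen. Arid3a was called without background correction (adjusted p = 0.0109) and with a stricter filter (adjusted p = 0.0335). Prss34, a mast cell and basophil protease, had the value 1.79 ± 0.45 (adjusted p = 0.243). Of 26 monocyte and macrophage genes, 0 were called, also adjusted over the list alone, and the median was -0.28 (camera adjusted p = 0.000296, and adjusted p = 0.434 with an estimated correlation). Under median scaling it was 0.23, below that of all genes. Of 22 miR-125 targets, 0 were called, with 4 lower and 1 higher adjusted over the list alone. Their median was -0.08 (adjusted p = 0.00848, and adjusted p = 0.254 with an estimated correlation) and 0.32 under median scaling, where the call ended (0.112), as it did without a filter (0.278).

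The mast cell and basophil list lay higher with miR-125a, at a median of 0.42 (adjusted p = 0.0415, and adjusted p = 0.850 with an estimated correlation). Of its 15 genes 0 were called, with 3 higher and 1 lower adjusted over the list alone. The shift rested on miR-125a array 3, where the list stood 0.90 above the mean of the dataset's arrays, and without that array the median was 0.07 (adjusted p = 0.965). The call also ended without empty-vector arrays 4 (0.162) or 6 (0.0805) with array weights (0.364) and, narrowly, with the block by order. The 14 miR-99 targets, which miR-125a does not share a seed with, lay higher by 0.27 (adjusted p = 0.0342, and adjusted p = 0.434 with an estimated correlation), with 0 called, also adjusted over the list alone. That call ended without miR-125a array 3 (0.319) or empty-vector arrays 5 (0.0569) or 6 (0.0920), under median scaling (0.233), without a filter (0.0840), with array weights (0.0943) and with the block by order (0.0509). The other 17 lists did not pass, with medians between -0.21 and 0.16 and a lowest adjusted p of 0.0796. Without miR-125a array 2, neutrophil maturation genes turned to -0.32 and passed (0.0103), and the lymphoid (0.0333), dendritic cell (0.0393), p53 (0.0289) and ribosome biogenesis (0.0392) lists passed as well. The lymphoid list also passed without empty-vector array 6 (0.0362), and downward under median scaling (0.0246), at a median of 0.24 against 0.47 for all genes.

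Set directly against each other, the cluster and miR-125a differed in 0 of 9389 genes by limma, with 430 at an unadjusted p under 0.05 and a lowest adjusted p of 0.724. With the block by order it was 0 too, with 588 at an unadjusted p under 0.05. The effects of the cluster and of miR-125a against their shared empty-vector arrays correlated across genes with Pearson's r of 0.67 and Spearman's rho of 0.64, where unchanged groups simulated against these controls gave r of 0.50. The covariance was 0.0337 against a simulated 0.0197, a difference of 0.0141. With 1 of the 3 controls given to one vector and the other 2 to the other, in 6 ways chosen after the results were seen, r lay between 0.16 and 0.24 and the covariance between 0.0120 and 0.0169. No control array is shared in these splits, so the noise of single control arrays does not give their covariances. A shift common to all 3 empty-vector arrays would stay in each split and is not excluded. Averaged, the splits take off the noise of the controls much as the simulation does. That they span the difference of 0.0141 is therefore no independent support. A side with 1 control is noisier, so r there cannot be compared with 0.67. Simulation and splits treated the cluster and miR-125a arrays as independent. Taken in the order of their numbers, their deviations correlated at 0.23, 0.48 and 0.29, which may also move the covariance. Arid3a, the call of the cluster comparison, had a negative value with both vectors.

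The comparison of miR-155 with the empty vector concerned another microRNA, known from blood cells, in the arrays of dataset A. The largest falls among the named genes were in stefin and neutrophil genes, with Stfa2 8.60-fold lower (log2 -3.10 ± 0.30, SE, 2 arrays against 3, limma adjusted p = 4.21e-05), followed by Cstdc4 (-3.05), Cstdc5 (-2.52), Ltf (-2.43 ± 0.24, adjusted p = 4.21e-05), Stfa1 (-2.38), the chitinase-like gene Chil4 (-2.24), Itgb2l (-2.14) and Csta2 (-2.06). Itgb2l was detected on 1 of the 2 miR-155 arrays. Rises were smaller, with Bcat1, an enzyme of branched-chain amino acid breakdown, at 2.95-fold (log2 1.56 ± 0.22, adjusted p = 0.00179), then Thy1 (1.29), Abhd8 (1.27), Cnrip1 (1.27), Igfbp7 (1.23), carbonic anhydrase Car2 (1.14), the chemokine gene Ccl3 (1.10) and Dipk1b (1.09). Of 10272 genes, 21 rose and 86 fell, with 921 at an unadjusted p under 0.05. Under median scaling 0 rose and 102 fell, while the median of all genes was -0.28. Without background correction Stfa2 was 4.64-fold lower and still called, and of the 30 named genes 6 moved in fold by over 1.5 times and 10 lost their call. With series matrix values Stfa2 was 4.19-fold lower, 9 moved and 11 lost their call, and without a filter 16 lost it and under median scaling 8.

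Of 25 neutrophil maturation genes, 10 fell with miR-155 and 0 rose, among them Ltf, Stfa1, Itgb2l and Chil3 (4.01-fold lower), and 14 fell adjusted over the list alone. The median was -0.53 (camera adjusted p = 1.64e-20, and adjusted p = 0.0571 with an estimated correlation). Of 25 monocyte and macrophage genes, 8 fell, among them Ms4a6d (-1.24), Gpnmb (-1.11), the macrophage surface receptor gene Adgre1 (-0.91) and F13a1 (-0.86), and 19 fell adjusted over the list alone. Their median was -0.72 (adjusted p = 7.97e-19, and adjusted p = 0.0662 with an estimated correlation). Of 25 miR-155 targets named in the literature, 5 fell, among them the cytokine receptor gene Il13ra1 (-1.29), the signalling genes Smad5 (-1.10) and Tab2 (-0.94) and the transcription factor Ets1 (-0.92), and 11 fell adjusted over the list alone. Their median was -0.47 (adjusted p = 1.52e-10, and adjusted p = 0.0514 with an estimated correlation). The other detected probe of Smad5 had the opposite sign. Smaller shifts passed for 12 dendritic cell genes (median -0.34, adjusted p = 0.00185, and adjusted p = 0.156 with an estimated correlation), with Cd86 (-0.82) called and 5 lower and 1 higher adjusted over the list alone. They passed too for 15 primary granule genes (-0.24, adjusted p = 0.0233, and adjusted p = 0.269 with an estimated correlation), with Fcnb (-1.61) called, also adjusted over the list alone. They passed last for 15 mast cell and basophil genes (-0.23, adjusted p = 0.0127, and adjusted p = 0.434 with an estimated correlation), with the receptor gene Fcer1a (-1.04) called, also adjusted over the list alone.

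The other 15 lists did not pass with miR-155, with medians between -0.48 and 0.10 and a lowest adjusted p of 0.0650. Among their members, the globin gene Hbb-bt (log2 -1.28) fell while Car2 rose among erythroid genes, Thy1 rose among lymphoid genes, Ets1 fell as a miR-125 target too, and Igf2bp3 (-1.18), detected on 1 of 2 miR-155 arrays and with 1 of its 2 other probes of the same sign, fell among let-7 targets. The count of 107 genes was 20 without miR-155 array 2 and 84 without array 1, and 58, 70 and 47 without empty-vector arrays 1, 2 and 3. Of the 30 named genes, 11 stayed called whichever array was left out. These were Cnrip1, Stfa2, Cstdc4, Cstdc5, Ltf, Stfa1, Chil4, Itgb2l, Csta2, Fcnb and Chil3. Adjusted p of the others reached values between 0.0676 for Bcat1 and 0.575 for Adgre1. The primary granule call ended without empty-vector array 2 (adjusted p = 0.0684) or miR-155 array 1 (0.241), and the mast cell call without empty-vector array 1 (0.142) or miR-155 array 1 (0.307). Median scaling also ended the primary granule call (0.177). Let-7 targets passed downward without empty-vector array 2 (0.00560), with every probe (0.00717) and under median scaling (0.0480), lymphoid genes downward with every probe (0.0146), and ribosome biogenesis genes upward without empty-vector array 1 (0.0197).

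**Figure D3:**
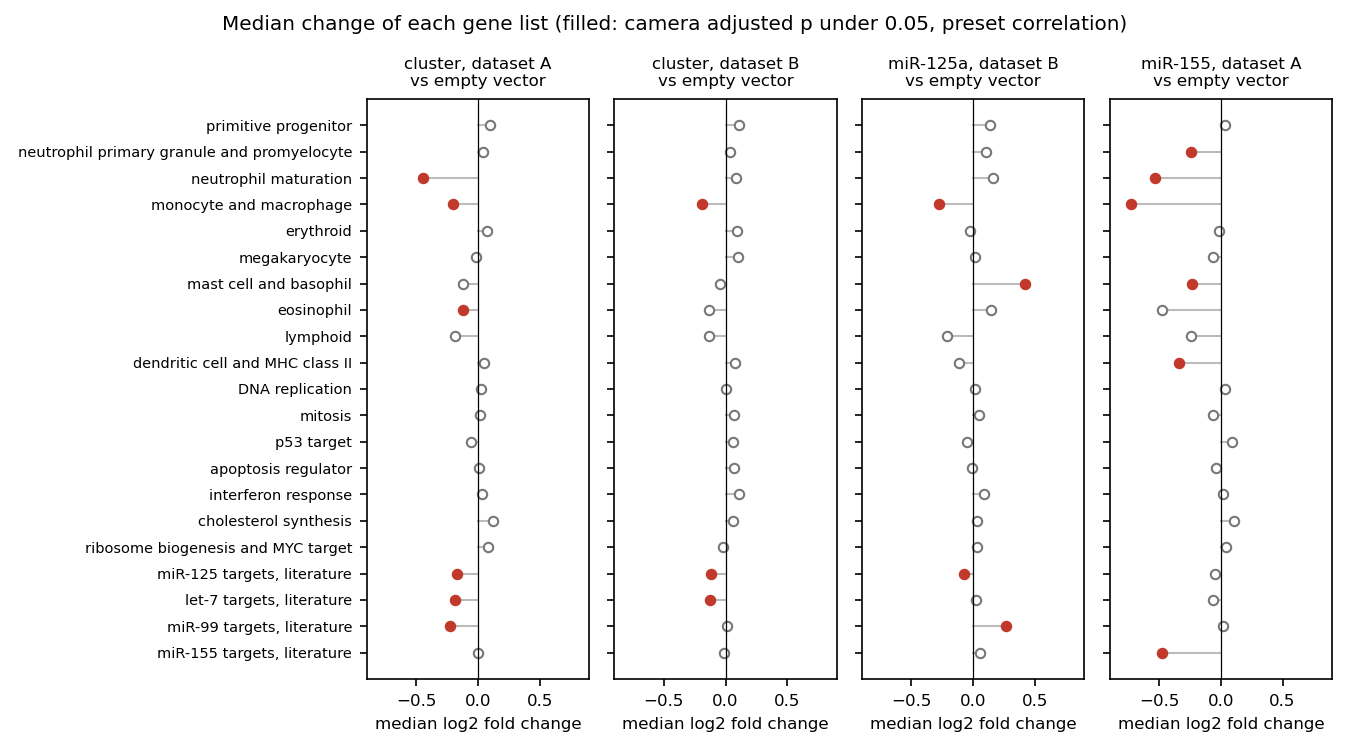
Median log2 fold change (horizontal axes) of the 21 gene lists in each comparison with the empty vector, filled where camera's adjusted p with the preset correlation was under 0.05. The neutrophil maturation list lay at -0.44 with the cluster in dataset A and -0.53 with miR-155, and the monocyte list lay below 0 in all 4 comparisons. Under median scaling the monocyte list was above 0 in dataset B, at 0.12 with the cluster and 0.23 with miR-125a. It still lay below the medians of all genes there, 0.31 and 0.47.

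The cluster was set directly against miR-155 in dataset A to show where these vectors differed. Rab34 was 6.30-fold higher with the cluster (log2 2.66 ± 0.18, SE, 3 arrays against 2, limma adjusted p = 1.17e-06), followed by Cited4 (2.06), the globin genes Hbb-bs (1.94) and Hbb-bt (1.89), which are near-identical, and the lipase gene Lpl (1.93). Tmem119 (-1.71), Slc46a3 (-1.05), Atp6v0a1 (-1.02), Btla (-1.01) and Ifi27l2a (-0.98) were lower. Of 10272 genes, 76 were higher and 12 lower, with 1051 at an unadjusted p under 0.05. Under median scaling 49 were higher and 1 lower, while the median of all genes was 0.22. Without background correction Rab34 was 2.89-fold and Cited4 2.19-fold higher, both still called, and of the 10 named genes 4 moved in fold by over 1.5 times and 4 lost their call. With series matrix values Rab34 was 2.65-fold higher, 7 moved and 4 lost their call, as 4 did without a filter and 4 under median scaling. The count of 88 fell to 16 without miR-155 array 2 and to 56 without the cluster array that carries no number. Of the 10 named genes, Rab34, Cited4, Hbb-bs, Hbb-bt and Tmem119 stayed called whichever array was left out. Adjusted p reached 0.0596 for Lpl, 0.492 for Slc46a3, 0.523 for Atp6v0a1, 0.124 for Btla and 0.188 for Ifi27l2a.

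Against their shared empty-vector arrays, the cluster and miR-155 both raised 5 genes, Bcat1, Eng, H1f10, Hmgn3 and Thy1, where independent lists would share 0.0675. Both lowered 16, among them Ltf, Camp, Chil1, Fcnb, Stfa1 and Stfa2, where independent lists would share 0.276. Unchanged groups simulated against these controls shared 0 calls in each of 20 runs. Groups without changes give few calls at all, so this cannot tell how far shared controls raise an overlap of real changes. Across genes the effects correlated with Pearson's r of 0.41 and Spearman's rho of 0.35, against r of 0.45 in the simulation. The covariance was 0.0275 against a simulated 0.0200, a difference of 0.00752. With the controls split in the same 6 ways, r lay between 0.06 and 0.14 and the covariance between 0.00597 and 0.0122. Part of the shared calls may come from the shared controls, as calls were not counted again with split ones. Comparisons that shared no arrays gave r of 0.11 for the cluster in dataset A with miR-125a, 0.05 for the cluster in dataset B with miR-155, and -0.00 for miR-125a with miR-155, with rho of 0.06, 0.00 and -0.03. The genes named here as shared were chosen after their values were seen.

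**Figure D4:**
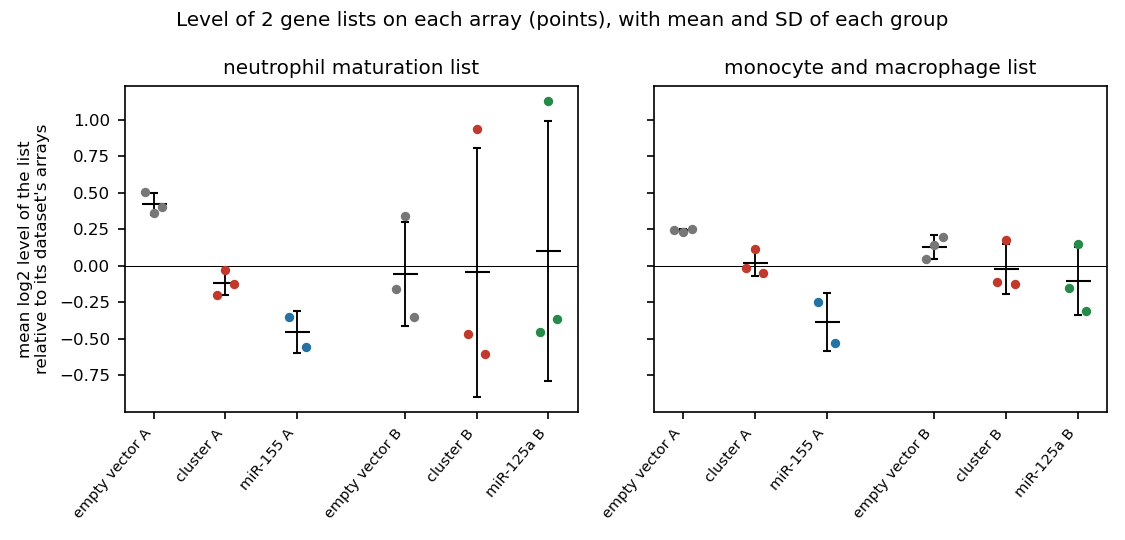
Mean log2 level of the neutrophil maturation list (left) and the monocyte and macrophage list (right) on each array (points), relative to the mean of its dataset's arrays, with the mean and SD of each group as lines. The neutrophil list lay between 0.36 and 0.50 on the empty-vector arrays of dataset A and between -0.20 and -0.03 on the cluster arrays, while in dataset B it reached 0.93 on cluster array 5 and 1.13 on miR-125a array 2.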

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

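The splits of the arrays were planned, and the tests of the neutrophil list, of the miR-155 arrays and of the arrays numbered 5 were chosen after their results were seen.

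Probes without a gene name, which no comparison of genes used, also carried signal. Of 2868 such probes tested by limma in dataset A, 4 were called with the cluster (3 higher, 1 lower), 9 with miR-155 (1 higher, 8 lower) and 3 for the cluster against miR-155 (3 higher). Probe ILMN_2756023 rose with the cluster (log2 1.61, adjusted p = 8.65e-05) and lay higher than with miR-155 (2.33), and ILMN_2609182 rose with the cluster (1.20) and with miR-155 (1.05). Probe ILMN_2624477 fell with the cluster (-0.90) and ILMN_2420341 with miR-155 (-1.95).

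For the cluster in dataset A, 1 of 10 splits of the 6 arrays called 66 genes or more, the real one, and the highest of the others called 0. For the cluster in dataset B, 1 of 10 splits reached the real count of 1, with 0 as the highest other, also among the splits that part all 3 pairs. For miR-125a, 10 of 10 splits reached the real count of 0, with 0 as the highest other. For the cluster against miR-125a it was 10 of 10, with a real count of 0 and a highest other of 3. Any split reaches a real count of 0, so both shares of 10 of 10 were fixed in advance and decide nothing. With 10 splits a share under 0.05 cannot be reached. For the difference between datasets the real count was 0 too, so 100 of 100 splits drawn reached it by definition. Of the 99 others, 96 called 0 genes and 3 called 2, 39 and 41, which may point to a structure of the arrays other than their groups and was not tested further.

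The neutrophil maturation list lay lower with the cluster in dataset A (median -0.44) and was not called in dataset B (0.09). A single array of dataset A as the source was excluded, since the median was at most -0.39 with any 1 array left out. Background correction or scaling stays open for the size of the shift, because the median was -0.20 with the series matrix values, although the list stayed called there. Spread between the arrays of dataset B stays open too, as the difference between datasets had a camera adjusted p of 0.0523. Without cluster array 5 the list stood at -0.37 in dataset B (camera adjusted p = 0.00552). That array was picked after its value was seen, and empty-vector array 5, which also lay high, was kept. A biological difference between the datasets was not tested.

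The count of genes called with miR-155 fell further without its array 2 than without its array 1. The loss of 1 array as such stays open as the source, since either fit rests on 1 miR-155 array. A larger count from array 2 may come from that array's own deviations, so the counts cannot decide. With 1 array left, no spread among miR-155 arrays enters the fit, so only a size is given. Changes carried by array 2 alone were excluded for the miR-155 target list by that size, a median of -0.45 from array 1 alone and -0.47 from both. They were excluded for the genes called from array 2 against 2 empty-vector arrays, as a set, since 40 of 40, 48 of 54 and 40 of 49 had the same sign on array 1 against the remaining one. Their median change there was at least 0.516 times that on array 2, while for each gene alone it stays open. Of the arrays of dataset A, miR-155 array 2 had the lowest share of detected probes (34.8%). Its mean correlation with the dataset's other arrays (0.983) was also the lowest. Whether the quality of that array explains the count was not tested. No biological explanation was tested.

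In dataset B the neutrophil maturation list lay highest on the array numbered 5 within the empty-vector arrays and within the cluster arrays, while the highest value of all, 1.13, was on miR-125a array 2. The mean excess of number 5 over the other numbers was 1.03, with 0.60 for the empty vector and 1.47 for the cluster. A difference between cultures that carried the same number may be the source, which stays open because 1 such number and 2 groups cannot decide it. Cluster array 5 deviated more like miR-125a array 2, at a correlation of 0.48, than like empty-vector array 5, at 0.19. No biological explanation was tested.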

How the results depend on the processing

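A block by the order of the numbers for miR-125a was chosen after the data were seen, and the other alternatives were planned. Without background correction limma called 41 genes with the cluster in dataset A (33 of them among the 66), 10 with it in dataset B, 7 with miR-125a, 56 with miR-155 and 47 for the cluster against miR-155. The series matrix gave 42 (33 of them among the 66), 10, 7, 56 and 46. Median scaling gave 25 (25 of them among the 66), 71 (68 higher) and 2176 (2173 higher), with 6 for the cluster against miR-125a, 50 for the cluster against miR-155 and 2 for the difference between datasets. Under it the median of all genes was -0.06, 0.31 and 0.47 in these first 3 comparisons, -0.28 with miR-155 and -0.39 for the difference. Without a filter 21, 37 and 28 genes were called with the cluster in dataset A, with miR-155 and for the cluster against miR-155. A stricter filter gave 3 with miR-125a, and a trended robust prior 26 with the cluster in dataset B and 18 with miR-125a. Median scaling set the median of all 45281 probes equal between arrays. Between 34.2% and 38.9% of these were detected per array in dataset B, so undetected probes set that level. The tested genes were thus not centred, and counts under this scaling carry the offset. The causes of the other differences were not tested. The remaining settings kept these counts within 1.5 times, apart from the replicate blocks and single arrays left out, which are given below.

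Leaving out 1 array gave 30 to 44 genes with the cluster in dataset A, 0 to 2 in dataset B, 20 to 84 with miR-155 and 16 to 60 for the cluster against miR-155. It gave 0 for miR-125a, for the cluster against miR-125a and for the difference between datasets. With 1 miR-155 array left, that array is assumed to vary like the other groups. The neutrophil maturation list with miR-125a turned from 0.16 to -0.32 (adjusted p = 0.0103) without miR-125a array 2 and was 0.34 without empty-vector array 5. No named gene turned its direction when called.

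In dataset A, on series matrix values, deviations of same-numbered empty-vector and cluster arrays correlated at -0.19, -0.03 and 0.36. Not every array correlated best with its own number, so the numbers were not taken as pairs there. Whether arrays of 1 number share a mouse, culture or day cannot be told from these values. The replicate block on series matrix values gave 48 genes for the cluster there (42 without it), 43 for miR-155 (56) and 29 for the cluster against miR-155 (46). In dataset B the replicate block, fitted without the miR-125a arrays, gave 0 genes in place of 1 and changed no list call. The replicate block by order gave 0 genes for miR-125a and for the cluster against miR-125a, as without it. Of 19 list calls, 19 were kept with all arrays normalized together, 18 without background correction, with the series matrix or with every probe, 16 with array weights, and 14 with median scaling or without a filter. The correlation of the cluster and miR-155 effects was 0.45 without background correction and with the series matrix. Signal over background limits dim genes, and a block by slide and the seed site tests were not run.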

Other observations

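The list tests of the direct comparisons of vectors were chosen after the results against the empty vector were seen, and were adjusted over 21 lists in each comparison. Set against miR-155, the cluster left the miR-155 targets named in the literature higher, at a median log2 difference of 0.44 over 25 genes (camera adjusted p = 2.46e-08), a call that held with an estimated correlation (adjusted p = 0.0243 with an estimated correlation). Of these genes 3 were called higher, the signalling gene Smad5 (adjusted p = 0.00343 by limma), Tspan14 (0.93) and the transcription factor Bach1 (0.99), and 9 adjusted over the list alone. The monocyte and macrophage list was higher too, at 0.49 (adjusted p = 5.26e-09; adjusted p = 0.0866 with an estimated correlation), with 0 of 25 genes called and 8 higher adjusted over the list alone. Neutrophil maturation genes were higher by a median of 0.28 (adjusted p = 0.000102; adjusted p = 0.150 with an estimated correlation), with Cd177 (1.13) and Chil3 (1.19) called of 25, and 8 adjusted over the list alone. The dendritic cell list (0.22, adjusted p = 0.00152; adjusted p = 0.0866 with an estimated correlation) held 1 call, the antigen presentation gene H2-Ab1 (1.02). The primary granule list was higher by 0.25 (adjusted p = 0.0172; adjusted p = 0.150 with an estimated correlation). The miR-99 targets were lower, at -0.25 (adjusted p = 0.00602; adjusted p = 0.279 with an estimated correlation). The primary granule call ended without the cluster array that carries no number (adjusted p = 0.0857) or miR-155 array 1 (0.153), and the miR-99 call without that cluster array (0.0886) or miR-155 array 2 (0.0586). Sizes depended on the preparation, with the miR-155 targets at 0.28 without background correction and 0.72 under median scaling, where the median of all genes was 0.22.

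Set against miR-125a, the cluster left the mast cell and basophil list lower by a median of -0.32 over 15 genes (camera adjusted p = 0.000814; adjusted p = 0.630 with an estimated correlation), with 0 called. This rested on miR-125a array 3, without which the median was -0.06 (adjusted p = 0.349), while without array 1 it was -0.48. The eosinophil list (-0.45, adjusted p = 0.0388; adjusted p = 0.648 with an estimated correlation), let-7 targets (-0.10, adjusted p = 0.0135; adjusted p = 0.630 with an estimated correlation) and miR-99 targets (-0.14, adjusted p = 0.00695; adjusted p = 0.630 with an estimated correlation) were lower as well. The p53 targets were higher by 0.12 (adjusted p = 0.0285; adjusted p = 0.630 with an estimated correlation). Each of these 4 calls ended with single arrays left out. The eosinophil call ended without cluster arrays 4 (adjusted p = 0.159) or 6 (0.270) or miR-125a arrays 2 (0.317) or 3 (0.149), and also without background correction (0.0604) or filter (0.157), with series matrix values (0.0699) and with array weights (0.145). The let-7 call ended without cluster array 6 (0.230) or miR-125a arrays 2 (0.0501) or 3 (0.0611), and its median was -0.21 without cluster array 5. The miR-99 call ended without cluster array 6 (0.0590) or miR-125a array 3 (0.149). The p53 call ended without cluster arrays 5 (0.161) or 6 (0.0590) or miR-125a arrays 1 (0.0935) or 3 (0.349), and with a block by the order of the numbers (0.0516). Of the members of these lists limma called 0, among 430 genes in all at an unadjusted p under 0.05.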
